A study of Danio rerio with 5 samples.

How the data were processed

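The series holds 5 arrays of the zebrafish ZF4 cell line, 3 from cells given 100 nM rapamycin and 2 from cells given the DMSO solvent, all taken at 48 h. Per the labels' protocols, total RNA was extracted, amplified and biotin-labelled with a 3' in vitro transcription kit, and the platform was the Affymetrix zebrafish gene chip. The deposited values are log2 expression values, 1 per probe set and array, and per the submitters' processing notes and the series design text they were made with RMA, which corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set. The version of RMA is not given in the sources used here. The log2 scale was read from the deposited values, which ran from 2.03 to 13.9. The design text names a class comparison in BRB Array Tools, whose output was not used here. RMA fits all arrays together and forces their distributions to be alike, so a change shared by most genes would not show in these values, and signals near the floor or the top of the scale are compressed. For arrays, their number limits the precision.

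Groups were taken from each sample's title and treatment label. The table held 15617 probe sets, of which 115 Affymetrix control probe sets were left out, leaving 15502 for testing. By the platform annotation 10795 of these had 1 gene symbol, 135 had several and 4572 had none. Symbols were updated through the Entrez ID in a current RefSeq gene table of the GRCz12tu assembly, where 10711 matched and 1 symbol changed. This gave 8793 genes, 1539 of them with more than 1 probe set. A gene was represented by its probe set with the highest mean over all 5 arrays, whatever the group, and probe sets with several symbols were never used to name a gene.

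Rapamycin was compared with DMSO with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with default settings, two-sided, with Benjamini-Hochberg adjustment over the 15502 probe sets and a threshold of 0.05. The fit had 3 residual degrees of freedom and a prior worth 1.93 more. SE is the moderated standard error of that fit. Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes, with 1 probe set per gene, all genes with a single symbol as the background and Benjamini-Hochberg adjustment over the 40 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera also counts only the 3 residual degrees of freedom of the fit. Its larger p can therefore reflect these few degrees of freedom, correlation between genes, or both. With 3 arrays against 2, the smallest two-sided exact permutation p for a single value is 0.1.

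These choices, the 40 lists and the alternatives were made before the data were examined, except where stated. The lists covered protein synthesis (cytosolic ribosomal proteins, ribosome biogenesis, translation factors, aminoacyl-tRNA synthetases), cell division (G2/M, G1/S, histones, p53 targets), the mTOR pathway, autophagy, lysosome, proteasome and heat shock proteins, energy and lipid metabolism (glycolysis, TCA cycle, oxidative phosphorylation, mitochondrial ribosome, fatty acid oxidation, fatty acid and cholesterol synthesis, nucleotide synthesis, ATF4 targets, glutathione), stress and signalling (endoplasmic reticulum chaperones, hypoxia, apoptosis, interferon, immediate early genes, growth factor signalling, circadian clock, spliceosome), actin, extracellular matrix, and 7 lists of markers of other cell types. In all, 1589 distinct list genes were measured. The lists were compiled from general knowledge of zebrafish gene names, so a list can miss members or hold one that acts elsewhere.

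The genes named were chosen by a fixed rule. The rule took up to 12 genes per direction with the largest change past the threshold and no overlap between groups. Where fewer passed it took those with the smallest unadjusted p, said not to pass, and placeholder symbols were skipped. It also took up to 4 members of each list with the smallest p and 30 genes tied to mTOR signalling, proliferation, autophagy, sterol control and the clock, whatever their values. The rule gave 186 genes, of which 129 are named in the text. Of the 30 genes fixed in advance, rptor, rictora, rictorb, fkbp1ab, rps6kb1a, tsc2, cdkn1a, cdkn1ba, srebf1, srebf2 and per1b had no probe set with a single symbol and were not analysed here.

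The steps were tested on simulated data with the same 15502 probe sets, 3 against 2 arrays, 200 changed probe sets and noise drawn from the fitted prior. Of the changed probe sets 37.2% were recovered at a log2 change of 0.5, 82.4% at 1, 95.6% at 2 and 98.2% at 4, and 5.09% of calls were unchanged probe sets. Over 10 simulations with no list shifted, 0.1 lists per simulation were called. Simulated noise was independent between genes, which real arrays need not be. The changed probe sets were split evenly over these sizes, and the large ones ease the adjusted threshold for the small ones. The shares recovered at 0.5 and 1 therefore need not hold for the real arrays. There nog1, at a log2 change of 1.94, did not pass (limma adjusted p = 0.0926).

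Alternatives were the replicate number as a block, an intensity trend in the variance prior with and without a robust prior, filters on dim probe sets at the median and the 25th percentile of brightness, quantile normalization applied again, centring each array on its median, array weights, leaving out each array in turn, other thresholds, the mean of a gene's probe sets, an estimated correlation and fry. The mean level of 18 hybridisation spike-in probe sets as a covariate was added after the data were seen. Lists were also set against 10000 random lists matched on brightness, within 100 ranks of each gene. Gene names were matched with Python 3.11.15 and pictures drawn with matplotlib 3.10.9.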

Results

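The measurements were transcript levels in ZF4, a fibroblast-like cell line derived from zebrafish embryos and grown here at 28 °C. Cells were kept for 48 h with 100 nM rapamycin, a macrolide that binds FKBP12 and inhibits the mTOR complex 1 kinase, or with its solvent DMSO. RNA from 3 rapamycin samples and 2 DMSO samples was hybridised to zebrafish gene chips, 1 array per sample. Pairs of arrays correlated across probe sets with Pearson's r from 0.992 to 0.997, and no pair was a duplicate. The number of arrays limits the precision of every value. The labels do not say whether the samples came from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical. Camera's p at the preset correlation sets a list's genes against all other genes. It rests on the spread over genes, so a very small value is no evidence of replication between samples.

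The comparison asked how rapamycin alters transcript levels in these cells. Genes of mitosis and DNA replication were lower as groups with rapamycin, with cyclin B1 (ccnb1) at 1.72-fold and cyclin A2 (ccna2) at 1.91-fold below DMSO. Neither of these lists, G2/M and G1/S, passed in camera with an estimated correlation (adjusted p = 0.139 for both). The estimated correlations were 0.018 for G2/M and -2.3e-04 for G1/S, beside the preset 0.01. A larger correlation thus did not end the G1/S call. Lists for oxidative phosphorylation, the mitochondrial ribosome, the proteasome, glycolysis, sterol synthesis and glutathione metabolism were also lower (adjusted p = 0.258 to 0.486 with an estimated correlation). Lists for cytosolic ribosomal proteins, ribosome biogenesis and translation factors were higher, by about 0.097 to 0.11 on the log2 scale at their medians (adjusted p = 0.258 to 0.504 with an estimated correlation). The estimated correlation was 0.18 to 0.28 for oxidative phosphorylation, the proteasome, ribosome biogenesis, sterol synthesis and the mitochondrial ribosome. It was 0.050 to 0.076 for ribosomal proteins, translation factors and glutathione, and -0.0069 for glycolysis. Where the estimate lay far above the preset 0.01, camera's p at the preset may be far too small. Of the 40 lists, 19 passed limma's camera test, 8 of them higher and 11 lower with rapamycin, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.139. Limma's fry, which asks whether a list's genes move on balance one way, passed 4 lists: G2/M (adjusted p = 0.0101), glycolysis (0.0229), G1/S (0.0411) and ribosomal proteins (0.0411). The single genes farthest apart for their spread included the clock repressor per2, 3.58-fold lower, and transgelin (tagln), 3.42-fold higher.

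No probe set passed an adjusted p of 0.05 in limma, out of 15502 tested, and the smallest adjusted p was 0.0534. The unadjusted p was under 0.05 for 1982 probe sets, 803 higher and 1179 lower, where chance alone would give 775.1. At an unadjusted p under 0.001 there were 118 probe sets, 43 higher and 75 lower, which stood for 90 genes. At an adjusted p under 0.10 there were 49 probe sets, 15 higher and 34 lower. The groups did not overlap for 4336 probe sets, 28.0% of those tested, against 20% by chance. The count of 0 moved with the handling of dim probe sets and of array scale: 40 probe sets (16 higher, 24 lower) passed among those above the median brightness, 35 (14 and 21) after quantile normalization was applied again, and 32 (10 and 22) after each array was centred on its median. Of the 24 genes described next, 17 passed under all 3 of these alternatives.

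The 12 genes with the smallest p in each direction did not pass the adjusted threshold, and all 24 had groups that did not overlap. They were chosen for a small p on these same arrays, so this separation is no added evidence. Per2, a light-responsive repressor of the circadian clock, stood at 8.20 ± 0.12 (SD, n = 3) with rapamycin and 10.04 ± 0.090 (SD, n = 2) with DMSO (adjusted p = 0.0534). Hsd17b12a, a reductase of very-long-chain fatty acid elongation, stood at 6.46 ± 0.10 (SD, n = 3) with rapamycin and 8.01 ± 4.3e-04 (SD, n = 2) with DMSO, 2.93-fold lower (adjusted p = 0.0534). Further down in the same direction, with log2 changes in brackets, came wdr76 (-1.14), lonrf4 (-1.04), the peroxiredoxin prdx1 (-1.02), dhrs13a.1 (-0.80) and zfp36l2 (-0.85), whose product binds AU-rich mRNAs and promotes their decay. The remaining lower genes were the cyclins ccna2 (-0.93) and ccnb1 (-0.79), the checkpoint ATPase trip13 (-0.86), prr11 (-0.70) and the cytokinesis factor ect2 (-0.69). Adjusted p for the 12 lower genes ran from 0.0534 to 0.0906.

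Among the higher genes, nog1, the secreted BMP antagonist noggin, stood at 8.77 ± 0.23 (SD, n = 3) with rapamycin and 6.82 ± 0.38 (SD, n = 2) with DMSO, 3.84-fold higher. Tagln, an actin-binding protein of smooth muscle, stood at 8.73 ± 0.25 (SD, n = 3) with rapamycin and 6.96 ± 0.15 (SD, n = 2) with DMSO. The other higher genes, with log2 changes, were ntd5 (1.66), the matrix metalloproteinase mmp9 (1.46), the dopa decarboxylase ddc (1.11) and the secreted Wnt inhibitor wif1 (0.98). The nucleolar helicase ddx21 (1.07), the 60S assembly GTPase gtpbp4 (0.99) and the initiation factor subunit eif3ea (0.63) belong to ribosome production and translation. Schip1 (0.84), tpbg1b (0.61) and the finTRIM gene ftr67 (0.54) completed the 12, with adjusted p from 0.0906 to 0.101.

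**Figure D1:**
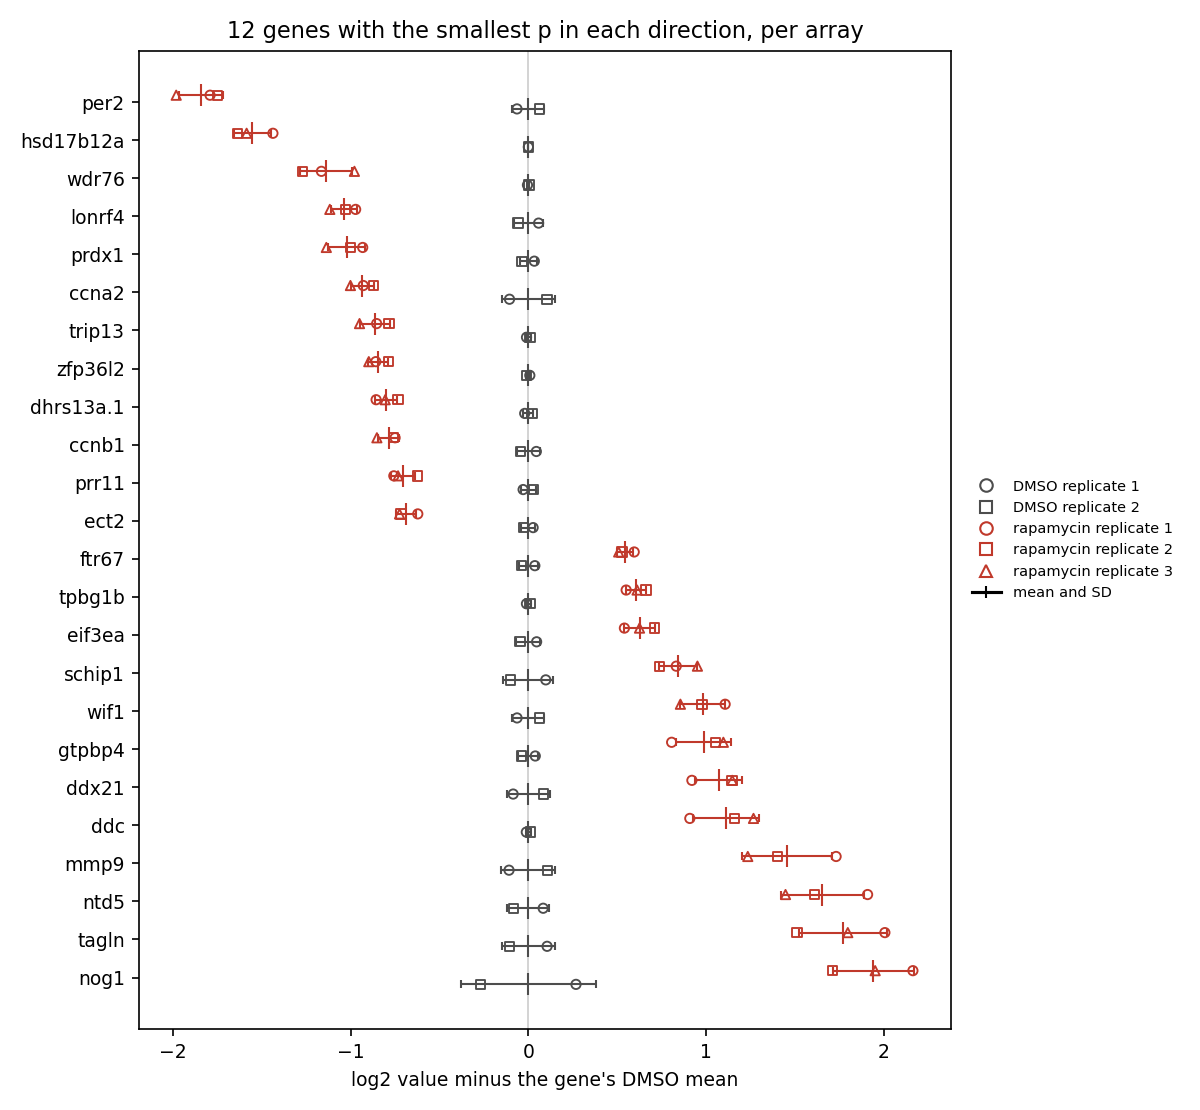
Horizontal axis: log2 value minus the gene's DMSO mean. Vertical axis: the 12 genes with the smallest p in each direction, with each of the 5 arrays as a symbol and each group's mean and SD as a bar. The rapamycin arrays lie apart from the DMSO arrays for all 24 genes, which were chosen for a small p on these arrays. Per2 (-1.84) and nog1 (1.94) lie farthest out.

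The G2/M and G1/S lists fell, while the histone and p53 target lists did not pass. In the G2/M and mitosis list, 64 of 72 measured genes were lower with rapamycin, with a median log2 change of -0.41 (camera in limma, adjusted p = 2.01e-19, and adjusted p = 0.139 with an estimated correlation). Relative to DMSO, the list mean per array was -0.37 ± 0.021 (SD, n = 3), against an SD of 0.0011 between the DMSO arrays (n = 2). Of its genes, 0 passed over all probe sets and 37 passed adjusted over the list alone, all lower. They included ccnb1, ccna2, ect2, the sororin gene cdca5 (-0.51, SE 0.051) and the mitotic kinase cdk1 (-0.66, SE 0.12). In the G1/S and DNA replication list, 52 of 63 genes were lower, with a median of -0.16 (adjusted p = 1.19e-06, and adjusted p = 0.139 with an estimated correlation), and 3 passed adjusted over the list alone. Those 3 were the replication licensing factor cdc6 (-0.85), the origin recognition subunit orc2 (-0.52) and the GINS subunit gins3 (-0.29); orc3 (-0.38) did not pass. Pcna (-0.36) and mki67 (-0.29), named in advance as proliferation markers, did not pass over all probe sets (adjusted p = 0.198 and 0.362). With 1 array left out mki67 ran from -0.41 to -0.18, and with the spike-in level as a covariate it turned to 0.0098. A 6-gene histone list had 5 members lower (median -0.13, range -0.20 to -0.046 with 1 array left out) and did not pass (adjusted p = 0.137), with h2ax (-0.46) past the threshold adjusted over the list alone.

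The ribosomal protein, ribosome biogenesis and translation factor lists rose by small amounts. For the cytosolic ribosomal proteins, 61 of 72 were higher, with a median of 0.097 (camera in limma, adjusted p = 6.85e-09, and adjusted p = 0.258 with an estimated correlation). Their list mean was 0.11 ± 0.019 (SD, n = 3) above DMSO, against an SD of 0.0012 between the DMSO arrays (n = 2), and 0 genes passed over all probe sets or adjusted over the list alone. The members with the smallest p were rpl28 (0.32), rpl6 (0.37), rpl5b (0.28) and rps7 (0.45). Among 98 ribosome biogenesis genes, 73 were higher, with a median of 0.098 (adjusted p = 1.46e-05, and adjusted p = 0.504 with an estimated correlation). There ddx21 alone passed adjusted over the list alone, while pno1 (1.04) and nop53 (0.98), both needed for ribosome assembly, were about as far apart, and bysl (0.29) was smaller. Among 58 translation factors, 42 were higher, with a median of 0.11 (adjusted p = 1.21e-04, and adjusted p = 0.428 with an estimated correlation). Of these, 6 higher genes and 1 lower gene passed adjusted over the list alone, among them eif3ea and the elongation factor subunits eef1b2 (0.49) and eef1db (0.63), with eif3ba (0.42). Leaving out DMSO replicate 2 ended the calls for ribosome biogenesis (median 0.046, adjusted p = 0.296) and translation factors (median 0.090, adjusted p = 0.0594), and without DMSO replicate 1 the biogenesis median was 0.19. The ribosomal protein median was 0.029 after quantile normalization was applied again (adjusted p = 0.00935).

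The lists for oxidative phosphorylation, the mitochondrial ribosome, the proteasome, glycolysis and the TCA cycle fell in camera, and none passed with an estimated correlation. In the oxidative phosphorylation list, 72 of 74 genes were lower, with a median of -0.24 (camera in limma, adjusted p = 6.76e-16, and adjusted p = 0.399 with an estimated correlation) and a list mean of -0.24 ± 0.059 (SD, n = 3). There 0 genes passed over all probe sets and 11 adjusted over the list alone, led by the cytochrome oxidase subunits cox7b (-0.43) and cox5ab (-0.33) and the ATP synthase subunits atp5mc1 (-0.35) and atp5f1d (-0.31). For the mitochondrial ribosome and its translation factors, 61 of 66 were lower, with a median of -0.18 (adjusted p = 1.30e-08, and adjusted p = 0.486 with an estimated correlation). Its members with the smallest p were mrpl42 (-0.48), gfm2 (-0.39), mrps28 (-0.38) and mrps5 (-0.34), and 0 passed adjusted over the list alone. In the proteasome list, 43 of 44 were lower, with a median of -0.20 (adjusted p = 1.26e-09, and adjusted p = 0.428 with an estimated correlation). The base ATPases psmc1a (-0.32) and psmc4 (-0.38) and the core subunits psma1 (-0.25) and psma4 (-0.35) had its smallest p, and 0 passed adjusted over the list alone. Glycolysis had 26 of 31 genes lower, with a median of -0.15 (adjusted p = 3.19e-04, and adjusted p = 0.258 with an estimated correlation). Here pfkfb4b (-0.36) passed adjusted over the list alone, and gapdhs (-0.37), eno1b (-0.35) and gpia (-0.28) did not. The TCA cycle list had 23 of 29 lower, with a median of -0.13 (adjusted p = 0.00983, and adjusted p = 0.428 with an estimated correlation). Malate dehydrogenase mdh1aa (-0.40), a cytosolic form of the enzyme, was the 1 gene past adjusted over the list alone. It was followed by the other cytosolic form mdh1ab (-0.68) and by suclg1 (-0.39) and sdhc (-0.43). The TCA cycle call ended after quantile normalization was applied again (median -0.092, adjusted p = 0.0528), which took the glycolysis median to -0.10. Without DMSO replicate 1 the median was -0.096 for the mitochondrial ribosome (adjusted p = 0.0166) and -0.057 for the TCA cycle (adjusted p = 0.0402). With the level of hybridisation spike-in controls as a covariate, calls ended for the mitochondrial ribosome (median -0.0071, adjusted p = 0.734), the TCA cycle (median -0.060, adjusted p = 0.215) and glycolysis (median -0.12, adjusted p = 0.0547).

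Lipid synthesis, redox and endoplasmic reticulum lists fell as well. Of 15 cholesterol synthesis genes and SREBP2 targets, 13 were lower, with a median of -0.29 (camera in limma, adjusted p = 0.00131, and adjusted p = 0.486 with an estimated correlation). The sterol demethylase cyp51 (-0.88, with 1 of its other probe sets opposite in sign), the synthase hmgcs1 (-0.47), acat2 (-0.44) and the squalene synthase fdft1 (-0.39) led it, and 0 passed adjusted over the list alone. Of 20 fatty acid synthesis genes and SREBP1 targets, 14 were lower, with a median of -0.26 (adjusted p = 0.0330, and adjusted p = 0.504 with an estimated correlation). There mid1ip1l (-0.62) passed adjusted over the list alone, followed by pgd (-0.50), elovl5 (-0.57) and acsl3b (-0.34). In the glutathione and NRF2 list, 26 of 33 were lower, with a median of -0.26 (adjusted p = 4.52e-05, and adjusted p = 0.402 with an estimated correlation). Prdx1, the glutathione transferase gstp1.2 (-0.86) and prdx2 (-0.48) passed adjusted over the list alone, and prdx3 (-0.33) did not. Of 41 endoplasmic reticulum chaperones and unfolded protein response genes, 28 were lower, with a median of -0.14 (adjusted p = 0.00979, and adjusted p = 0.504 with an estimated correlation). Its smallest p belonged to fkbp10b (-0.66), herpud1 (-0.20), pdia4 (-0.38) and sec11a (-0.48), and 0 passed adjusted over the list alone. Leaving out DMSO replicate 2 ended the cholesterol call (median -0.19, adjusted p = 0.0594) and took the endoplasmic reticulum median to -0.080. The cholesterol median was -0.18 without rapamycin replicate 1, and that of glutathione -0.17 without DMSO replicate 1. The fatty acid call ended without DMSO replicate 1 (adjusted p = 0.0896) or DMSO replicate 2 (adjusted p = 0.218). After quantile normalization was applied again, adjusted p was 0.0526 for fatty acid synthesis and 0.0827 for the endoplasmic reticulum list, and among probe sets above the median brightness it was 0.0651 and 0.107. The mean of a gene's probe sets gave 0.0604 for fatty acid synthesis. The spike-in covariate ended the calls for fatty acid synthesis (median -0.18, adjusted p = 0.0662) and the endoplasmic reticulum list (median -0.12, adjusted p = 0.0551), and with 1 array left out elovl5 ran from -0.82 to -0.33.

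Cytoskeletal, signalling and skeletal marker lists were higher. In the actin cytoskeleton and adhesion list, 43 of 61 genes were higher, with a median of 0.077 (camera in limma, adjusted p = 0.00548, and adjusted p = 0.258 with an estimated correlation). Tagln, tagln2 (0.62) and profilin pfn1 (0.79) passed adjusted over the list alone, and cdc42 (0.24) did not. In the growth factor and FoxO list, 31 of 46 were higher, with a median of 0.092 (adjusted p = 0.00986, and adjusted p = 0.486 with an estimated correlation). Its smallest p belonged to the ERK phosphatase dusp6 (0.57) and the receptors fgfr3 (0.69), met (0.92) and fgfr4 (0.98), and 0 passed adjusted over the list alone. Of the 7 lists of cell type markers, 3 passed. Cartilage and bone markers had 28 of 31 higher, with a median of 0.12 (adjusted p = 1.21e-04, and adjusted p = 0.428 with an estimated correlation), led by the transcription factors msx2b (0.71), dlx3b (0.79) and prrx1a (0.20). Liver, gut and pancreas markers had 33 of 41 higher, with a median of 0.080 (adjusted p = 0.0102, and adjusted p = 0.615 with an estimated correlation), led by hnf4a (0.24) and apoa4a (0.19), both below the array medians in signal. Endothelium and blood markers had 24 of 30 higher, with a median of 0.075 (adjusted p = 0.0221, and adjusted p = 0.527 with an estimated correlation), led by mpx (0.32, 2 of its other probe sets opposite in sign) and gata1a (0.12). In these 3 marker lists 0 genes passed adjusted over the list alone, and for the last 2 the list means of the groups overlapped. Dim probe sets were higher in general, with a median change of 0.018 to 0.050 in brightness deciles 1 to 5. Among random lists matched on brightness, cartilage and bone lay at percentile 99.96, liver and gut at 97.8 and endothelium at 95.6. Without DMSO replicate 1, calls ended for growth factor signalling (median 0.033, adjusted p = 0.360), liver and gut (median 0.021, adjusted p = 0.765) and endothelium (median 0.025, adjusted p = 0.0896), and the cartilage and bone median was 0.062. Leaving out DMSO replicate 2 ended the actin call (median 0.040, adjusted p = 0.0799) and took the medians to 0.15 for growth factor signalling and 0.14 for liver and gut. Leaving out rapamycin replicate 2 ended the endothelium call (median 0.035, adjusted p = 0.152) and gave a growth factor median of 0.059. Above the median brightness the medians were 0.26 for growth factor signalling and 0.20 for cartilage and bone, and above the 25th percentile that of endothelium was 0.12. After quantile normalization was applied again, the calls for endothelium (median 0.042, adjusted p = 0.257) and liver and gut (median 0.035, adjusted p = 0.236) ended, and above the median brightness these 2 lists had fewer than 5 genes left and were not tested. The spike-in covariate ended the calls for cartilage and bone (median 0.024, adjusted p = 0.215), endothelium (median 0.046, adjusted p = 0.173) and growth factor signalling (median -0.031, adjusted p = 0.734), whose median turned though its test still pointed higher, and it turned the liver and gut list (median -0.034, adjusted p = 0.561). With 1 array left out mpx ran from 0.16 to 0.49 and prrx1a from 0.13 to 0.27.

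**Figure D2:**
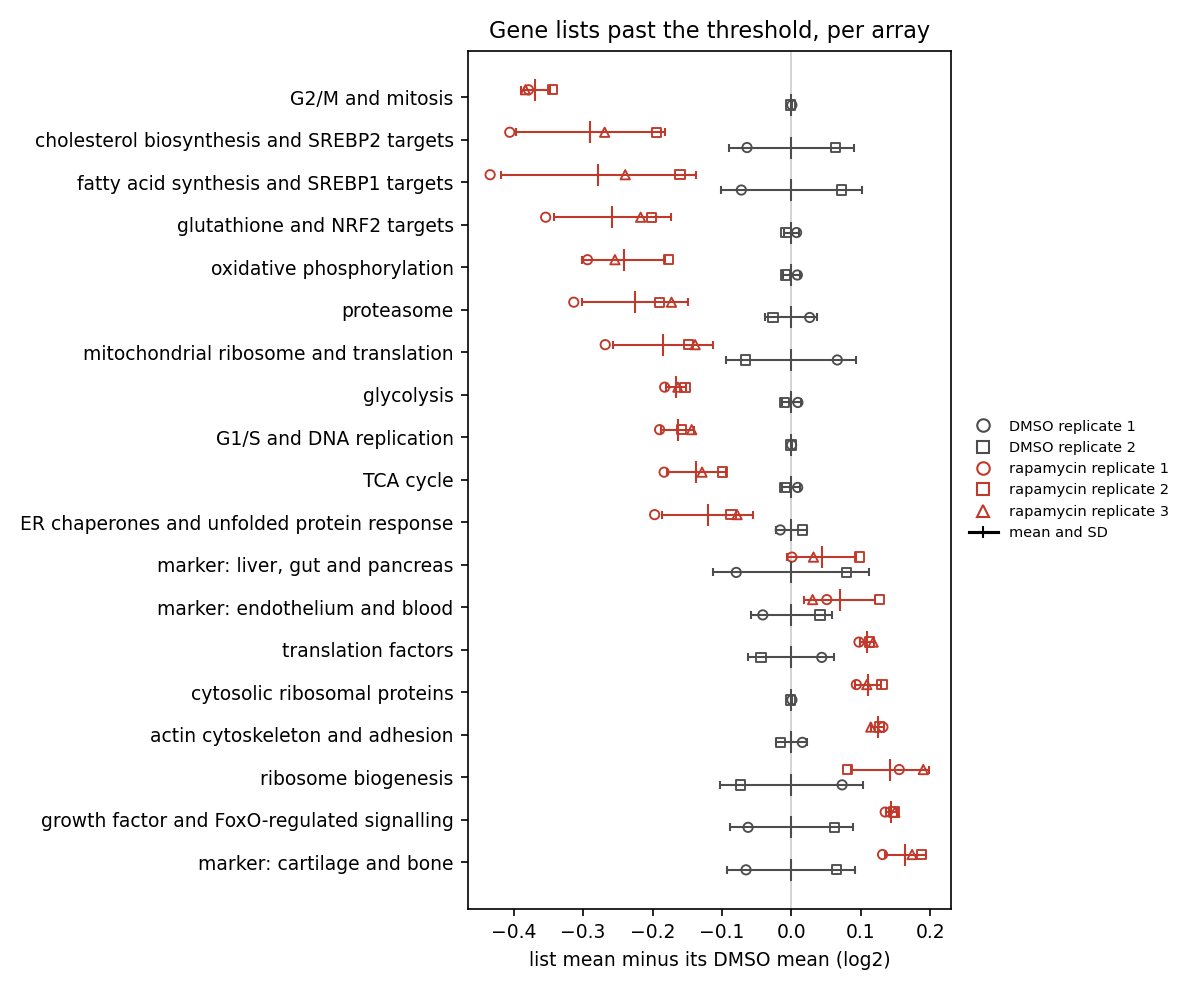
Horizontal axis: mean log2 value of a list's genes on each array, minus the list's DMSO mean. Vertical axis: the 19 lists past the threshold, with each of the 5 arrays as a symbol and each group's mean and SD as a bar; the G2/M list lies lowest with rapamycin (-0.37), and the liver and gut and the endothelium lists overlap between groups.

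Transcripts of the mTOR pathway itself did not pass as a list. Of 48 components, 25 were higher and 23 lower, with a median of 0.0040 (adjusted p = 0.694, and adjusted p = 0.743 with an estimated correlation), and the regulatory subunit pik3r3b (-0.91) was the 1 gene past adjusted over the list alone. With 1 array left out the list median ran from -0.013 to 0.022. The mTOR kinase gene itself stood at 5.68 ± 0.18 (SD, n = 3) with rapamycin and 5.65 ± 0.020 (SD, n = 2) with DMSO (adjusted p = 0.913). Its complex partner mlst8 (-0.025), the rapamycin-binding fkbp1aa (-0.069), the S6 kinase rps6kb1b (0.16), its substrate rps6 (0.11) and the repressors eif4ebp1 (0.29) and eif4ebp3l (0.20) did not pass. Neither did ddit4 (0.0057) and myca (-0.079), both below the array medians in signal. The remaining genes fixed in advance also did not pass: ccnd1 (0.23), hif1ab (-0.10), foxo3b (-0.37), ulk1a (-0.042), sqstm1 (-0.081) and map1lc3b (0.093). The other probe sets of mlst8, ccnd1 and foxo3b had the opposite sign. With 1 array left out these values moved by over 1.5 times for many: eif4ebp1 from 0.089 to 0.49, eif4ebp3l from 0.075 to 0.33, rps6kb1b from 0.057 to 0.27, ccnd1 from 0.011 to 0.38, foxo3b from -0.45 to -0.23, hif1ab from -0.16 to -0.058, sqstm1 from -0.14 to -0.020 and map1lc3b from 0.027 to 0.18. So did mtor, fkbp1aa, ulk1a, mlst8, ddit4 and myca, all under 0.1 in size with all arrays kept. Of these, mtor ran from -0.062 to 0.11, fkbp1aa from -0.14 to 0.021 and ulk1a from -0.14 to 0.058, so their sign turned. Myca reached -0.16. Of the 30 genes fixed in advance, 19 were measured through a single symbol. The autophagy list (median 0.050, adjusted p = 0.137) and the lysosome list (median -0.074, adjusted p = 0.0763) did not pass, with 0 genes past adjusted over the list alone. With 1 array left out their medians ran from 0.0030 to 0.069 and from -0.093 to -0.038. Without rapamycin replicate 3 the lysosome list passed (median -0.093, adjusted p = 0.0344).

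In the circadian clock list, 20 of 30 genes were lower, with a median of -0.055, and the list did not pass (adjusted p = 0.0800, and adjusted p = 0.605 with an estimated correlation). Leaving out rapamycin replicate 2 brought it past the threshold (adjusted p = 0.0394), and its median ran from -0.075 to -0.032 with 1 array left out. Of its genes, 3 passed adjusted over the list alone, all lower: per2, the photolyase-family gene cry5 (-1.11, SE 0.11) and the repressor nfil3-6 (-1.47, SE 0.16). Clockb (0.24), of the activating arm, did not pass.

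The other lists did not pass camera in limma, and 0 of their genes passed over all probe sets. The ranges given here are those of the median with 1 array left out. For ATF4 targets (median -0.057, range -0.19 to -0.044, adjusted p = 0.0527), the cystathionine lyase cth (-0.68) passed adjusted over the list alone. So did eef1e1 (-0.50) and wars1 (-0.34) among aminoacyl-tRNA synthetases (median -0.028, range -0.12 to 0.0035, adjusted p = 0.250). Among p53 targets (median 0.052, range 0.035 to 0.073, adjusted p = 0.312) it was gadd45aa (-1.35), and among hypoxia targets (median -0.042, range -0.066 to 0.0076, adjusted p = 0.332) it was the collagen hydroxylase p4ha2 (-0.47). For heat shock proteins (median 0.0087, range -0.041 to 0.019, adjusted p = 0.890), hspe1 (-0.51), hspa8b (-0.69) and the chaperonin subunit cct6a (0.43) passed adjusted over the list alone. In the interferon list (median -0.0043, range -0.041 to 0.043, adjusted p = 0.909), isg15 (-0.96) did so. The collagen and matrix list (median -0.013, range -0.018 to 0.0072, adjusted p = 0.909) had mmp9 higher and p4ha2 lower past that threshold. With 0 genes past adjusted over the list alone stood the spliceosome (median -0.052, range -0.057 to -0.031, adjusted p = 0.0762), purine and pyrimidine synthesis (median -0.043, range -0.096 to 0.0044, adjusted p = 0.198), fatty acid oxidation (median -0.028, range -0.067 to -0.013, adjusted p = 0.536), immediate early genes (median 0.017, range -0.066 to 0.11, adjusted p = 0.357) and apoptosis (median 0.048, range 0.0049 to 0.080, adjusted p = 0.542). The same held for markers of muscle (median 0.079, range 0.030 to 0.081, adjusted p = 0.0774), neurons and glia (median 0.033, range 0.0053 to 0.061, adjusted p = 0.138) and epithelium (median 0.049, range -0.011 to 0.084, adjusted p = 0.280). Of 30 muscle markers 22 were higher, and the smallest p belonged to acta1a (1.45), myf5 (-0.33) and ckma (-0.37). Of 33 epithelial markers 24 were higher, and the smallest p belonged to lye (-1.49), cldni (-1.09) and krt1-19e (0.25, its other probe set opposite in sign). With 1 array left out myf5 ran from -0.50 to -0.16 and ckma from -0.54 to -0.19. Among pigment cell and neural crest markers (median 0.073, range 0.021 to 0.12, adjusted p = 0.158), crestin (-0.50) and snai2 (0.42) passed adjusted over the list alone in opposite directions. Some of these lists passed under an alternative. ATF4 targets did so without rapamycin replicate 1 (median -0.19, adjusted p = 0.00105), without DMSO replicate 2 (median -0.13, adjusted p = 0.0460), with array weights (median -0.065, adjusted p = 0.0285) and above the 25th percentile of brightness (median -0.16, adjusted p = 0.0456). Leaving out DMSO replicate 2 also brought past the threshold aminoacyl-tRNA synthetases (median -0.12, adjusted p = 0.0219), immediate early genes (median 0.11, adjusted p = 0.0262), the spliceosome (median -0.042, adjusted p = 0.0262), neurons and glia (median 0.061, adjusted p = 0.0499) and pigment cells (median 0.12, adjusted p = 0.0471). Muscle markers passed above the median brightness (median 0.22, adjusted p = 0.0150) and above the 25th percentile (median 0.10, adjusted p = 0.0201). Of the 40 lists, 4 differed in sign among median, mean and test, none of them past the threshold.

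Hybridisation spike-in controls, added to each sample in fixed amounts, were higher on the rapamycin arrays, at 9.24 ± 0.11 (SD, n = 3) against 8.71 ± 0.33 (SD, n = 2). The exact permutation p of 0.1 is the smallest that groups of 3 and 2 allow. With this level as a covariate 10 of the 19 list calls remained, 0 probe sets passed, and the 9 calls lost are given with their lists. Among calls that remained, medians moved by over 1.5 times for ribosome biogenesis (0.18), G1/S (-0.10) and glutathione (-0.13). Splitting the 5 arrays into 3 and 2 in the other ways called up to 18 lists. The split with 18 kept both DMSO arrays together against 2 rapamycin arrays, so it holds part of the real difference. Splits that parted the DMSO arrays called 5 to 9 lists. With 10 splits the number of lists called cannot by itself set the 2 groups apart.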

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

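The tests on spike-in level and on brightness-matched lists were chosen after the results were seen, and the splits of the arrays were not. Spike-in controls, which no comparison of genes uses, were 0.53 higher on the log2 scale on the rapamycin arrays, for 18 of 18 probe sets, and they stand here because the planned comparison leaves these controls unused and their signal lay above that of the control arrays. The DMSO arrays were at 8.48 and 8.94, and the rapamycin arrays at 9.30, 9.11 and 9.31. The 24 poly-A control probe sets, equally unused, were 0.11 higher with rapamycin, at 4.26 ± 0.016 (SD, n = 3) against 4.15 ± 0.081 (SD, n = 2). The exact permutation p was 0.1, the smallest these groups can give. Their mean signal lay below the array medians, where tested probe sets of about that brightness (decile 4) had a median change of 0.050. The 3' to 5' difference of gapdh, a sign of RNA integrity, was 0.64 with rapamycin and 0.67 with DMSO (exact permutation p = 0.8).

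The 135 genes of the 2 cell cycle lists were lower with rapamycin by a mean log2 change of -0.27. A trend with the spike-in level would need the list mean to follow that level among arrays of 1 group. That slope over the gap between groups gave -0.013 (95% interval -0.11 to 0.083), short of the observed change, and the DMSO arrays, whose spike-in levels lay apart, differed by -0.0012. Random lists of the same brightness reached no lower than a median of -0.12, against -0.23, a percentile of 0. A step between the groups, such as a hybridisation batch, would leave no slope within a group, so the slope cannot speak to it. Batches are not given in the sources used here, so one aligned with the groups and rapamycin cannot be told apart. An effect of rapamycin on division may account for the change, which stays a hypothesis, since it was found and tested on the same arrays.

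The 228 genes for ribosomes and translation were 0.12 higher, and the 184 genes for the mitochondrial machinery and proteasome had a mean change of -0.22. Random lists of the same brightness argue against a shift shared by all bright genes, with percentiles of 100 and 0. Yet after quantile normalization was applied again the ribosomal protein median was 0.029 in place of 0.097. Part of that list's rise thus cannot be told apart from array scale. The translation factor median was 0.13 there, against 0.11. The spike-in slope gave -0.064 (95% interval -0.29 to 0.16) for the first group, opposite in sign to its change, and -0.099 (95% interval -0.43 to 0.23) for the second. With the spike-in level as a covariate camera still passed ribosomal proteins, translation factors and ribosome biogenesis (medians 0.094, 0.15 and 0.18) and oxidative phosphorylation and the proteasome (-0.18 and -0.17), but not the mitochondrial ribosome (-0.0071). Both 95% intervals between arrays still hold the observed change. With 5 arrays a trend with the spike-in level and rapamycin thus cannot be told apart for either group. For the second group the trend could account for part of the change.

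Over the 10 splits of the 5 arrays into 3 and 2, the real one gave 19 lists past the threshold and the highest other gave 18, so 1 split of 10, the real one, reached that count. Of probe sets with an unadjusted p under 0.001 the real split gave 118 and the highest other 39 (again 1 split of 10). The 10 splits are too few for a share under 0.05. The split with 18 lists put rapamycin replicate 3 with both DMSO arrays, so part of the real difference remained in it. The same holds for the splits with 13 and 16 lists, the last of which gave the 39 probe sets. Splits that parted the DMSO arrays gave 5 to 9 lists.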

How the results depend on the processing

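The spike-in covariate was chosen after seeing the data, and all other alternatives before. The count of 0 probe sets and genes became 40 and 30 above the median brightness, 35 and 28 after repeated quantile normalization, 32 and 26 with centred arrays, 3 and 2 above the 25th percentile of brightness, 2 and 2 with a trended robust prior or with array weights, 118 and 90 at an unadjusted p under 0.001, and 49 and 37 at an adjusted p under 0.10. Testing fewer probe sets is part of the filters' effect, and the cause was not tested for the rest. The first 3 of these shared 22 genes. The count stayed at 0 with a trended prior, the mean of a gene's probe sets, the spike-in covariate and each array left out (smallest adjusted p 0.193 to 0.441), and when a log2 change of at least 1 was asked for. The 19 list calls became 0 with an estimated correlation, 4 with fry and 10 with the spike-in covariate, and 15 to 20 with 1 array left out, of which 14 to 19 were among the 19. Without 1 DMSO array the lone one was assumed to vary like the rapamycin arrays. With a replicate block 0 probe sets passed (smallest adjusted p 0.356), all 19 list calls remained and the lysosome list (adjusted p = 0.0318) and the spliceosome (0.0393) were added. Replicate 3 existed for rapamycin alone, so the block took up that array. Its log2 changes equal those without rapamycin replicate 3 (-0.062 for mtor in both) and are no separate check. Of the 19, 15 remained above the median brightness, 14 after repeated quantile normalization and 18 with the mean of a gene's probe sets. By the labels the samples share only a number, and deviations from the group means correlated at 0.130 and 0.092 for numbers 1 and 2. With 2 DMSO arrays their deviations are mirror images, so the unlike numbers among these gave -0.130 and -0.092. Rapamycin replicate 3 with DMSO replicate 2 gave 0.054, and these values cannot decide on a pairing. Of the 150 measured genes named in these texts, 138 kept their sign under the alternatives run, as did the test of 29 of 40 lists. Log2 changes (for lists, medians) where a gene's change or a list's test turned were, with the spike-in covariate, aminoacyl-tRNA synthetases 0.011, fatty acid oxidation -0.0059, heat shock proteins -0.0080, immediate early genes -0.099, matrix 0.015, interferon -0.028, epithelium -0.012, pigment cells 0.0039, liver and gut -0.034, ddit4 -0.0038, mki67 0.0098, mtor -0.076, myf5 0.065, tefa 0.019, xpc 0.0070 and cry-dash 0.10; above the median brightness, heat shock proteins 0.0067; above the 25th percentile, heat shock proteins 0.0087 and interferon -0.041; after repeated quantile normalization, heat shock proteins 0.036, interferon -0.0022, ddit4 -0.016 and mlst8 0.017; with the replicate block, matrix 0.0072, interferon -0.018, mtor -0.062 and fkbp1aa 0.021; with the mean of a gene's probe sets, interferon -0.039 and mlst8 0.065; with fry, interferon -0.0043; with centred arrays, ddit4 -0.015; with array weights, bmal1b 0.015. Growth factor signalling was the 1 called list whose median turned (-0.031 with the spike-in covariate) while its test did not. The ranges with 1 array left out, where a turn occurred, were aminoacyl-tRNA synthetases -0.12 to 0.0035, mTOR components -0.013 to 0.022, fatty acid oxidation -0.067 to -0.013, heat shock proteins -0.041 to 0.019, apoptosis 0.0049 to 0.080, immediate early genes -0.066 to 0.11, matrix -0.018 to 0.0072, interferon -0.041 to 0.043, epithelium -0.011 to 0.084, ulk1a -0.14 to 0.058, mtor -0.062 to 0.11, fkbp1aa -0.14 to 0.021, bmal1b -0.10 to 0.060, cpdp -0.044 to 0.17, and the cause was not tested. The linear-scale alternative was not run because the values are log2. An unadjusted p under 0.05 was found for 1.42% of the dimmest decile of probe sets and 25.9% of the brightest.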

Other observations

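The tests in this part, and its genes other than nog1, wif1, per2, cry5, nfil3-6, clockb and xpc, were chosen after the values were seen. Secreted and intracellular antagonists of Wnt and BMP signalling stood out among the higher genes. The Wnt antagonist dkk1b was at 7.93 ± 0.37 (SD, n = 3) with rapamycin and 5.96 ± 0.27 (SD, n = 2) with DMSO, 3.93-fold higher (limma adjusted p = 0.109 over all probe sets). Beside nog1 and wif1 came dkk3b (0.60), the BMP pseudoreceptor bambia (1.18), the inhibitory Smads smad6a (0.61) and smad7 (0.74), and fstl1b (0.61). Of 18 antagonists measured, 17 were higher, with a median log2 change of 0.36, and 7 passed adjusted over the list alone, a list drawn up from genes already noticed and so no independent evidence. Leaving out the 8 genes noticed first, the other 10 had a median of 0.080, with 9 higher, camera p = 0.0344, p = 0.114 with an estimated correlation, and 0 past adjusted over the list alone. Several of the 10 lay below the array medians in signal. Probe sets in general were higher there, with a median change of 0.030 to 0.050 in brightness deciles 2 to 5. A rise of the whole antagonist group thus stays open, and sost (0.56) was the largest change among the 10, running from 0.28 to 0.84 with 1 array left out.

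Other single genes with large differences lay outside the rule. The stearoyl-CoA desaturase scd was 3.59-fold lower but varied within groups, at 7.33 ± 0.79 (SD, n = 3) against 9.18 ± 0.83 (SD, n = 2), with adjusted p = 0.304 in limma. Foxm1, a transcription factor that drives mitotic genes, had a log2 change of -1.14 (SE 0.11), and the kinase pim1 one of 1.19 (SE 0.15).

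The lower per2, cry5 and nfil3-6 form a clock-linked pattern with a mean log2 change of -1.47. A faulty probe set is argued against for per2 and nfil3-6 by their other probe sets, at -1.37 (SE 0.14) and -0.44 (SE 0.081), and stays open for cry5, whose other probe set was at -0.22 (SE 0.10) and did not pass an unadjusted threshold of 0.05. The spike-in slope gave -0.087 (95% interval -1.21 to 1.04). That interval, on 2 residual degrees of freedom, ends short of the whole change but reaches most of it. These genes were also picked as those past the threshold over the list alone, which can enlarge their change. A trend with the spike-in level could thus account for a large part. Zebrafish cells respond to light directly, so less light on the rapamycin dishes could lower light-induced genes such as per2 and cry5. Yet of 7 other light-induced genes (cry1a, tefa, cry-dash, cpdp, xpc, ddb2 and neil1) only 4 were lower, which decides nothing. A shift of clock phase stays as open, with 3 of 6 activating genes (clocka, clockb, bmal1a, bmal1b, bmal2 and npas2) higher. Light and hour of harvest are not given in the labels, so they and an effect of rapamycin cannot be told apart.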
